A study of Mus musculus with 4 samples.

How the data were processed

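The series measured total RNA of mouse liver, labelled with biotin and hybridised to Affymetrix expression arrays with several probes per transcript (a probe set). It held 4 arrays, 2 taken 48 h after a sham operation and 2 taken 48 h after partial hepatectomy. The design text calls them biological duplicates. Whether each array held RNA of 1 animal or of a pool is not given in the sources used here, and p-values measure the spread between these arrays.

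The values were intensities on a linear scale as deposited by the authors, 1 signal per probe set and array, made with GCOS 1.4, per the submitters' processing notes. The settings of that software, detection calls and scan dates are not given in the sources used here, so no batch could be tested. After trimming 2% of the values at each end, the mean signal of every array was 500, which shows a scaling of each array to a common mean before deposit. The median signal was 48.7 and 47.6 on the sham arrays and 57.5 and 46.4 on the hepatectomy arrays. RNA integrity was looked at through control probe sets at both ends of 2 transcripts. The 3' to 5' signal ratio of beta-actin was 2.75 and 2.35 in the sham arrays and 2.40 and 2.02 in the hepatectomy arrays, and that of Gapdh was 1.66 and 1.54 against 1.73 and 1.45, so neither separated the groups.

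Of 45101 probe sets, 64 controls were left out. Gene symbols came from the platform annotation: 34958 of the other 45037 probe sets had 1 symbol, 932 had several and 9147 had none or were not listed, and no gene was named from a probe set with several. The 1-symbol probe sets named 18194 genes. Matching by Entrez identifier updated 0 symbols, and 204 probe sets had no match. No genome coordinates were used here.

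Signals were turned to log2 after adding an offset of 8.57, the 20th percentile of all values, so fold changes of dim genes are understated. The authors' scaling was kept. Probe sets with a mean log2 value under the 40th percentile (5.09) were left out, which kept 27022. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment over all 27022 probe sets. A probe set was called at an adjusted p of 0.05. The model had 2 residual degrees of freedom and a prior of 6.02. Each gene was represented by its tested 1-symbol probe set with the highest mean. Of the 586 called genes 250 had several tested probe sets, every one called alike in 99 of these, and none had a probe set called the other way. Means and SDs are of the authors' signals; fold changes and their standard errors are on the log2(signal + offset) scale.

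Where both arrays of a group lay under 20.4, the highest signal of 27 Bacillus subtilis control probe sets, the fold is given as a lower bound against that level. This floor was chosen after seeing the data. It applied to 41 genes that rose and 1 that fell.

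Before the data were examined, 35 gene lists of pathways and cell types with 973 distinct genes, the rule for named genes, the tests and the alternative settings were fixed. A probe set was found for 891 of the genes. For each list the called members were counted, also with adjustment over the list alone, and camera was run with a preset correlation of 0.01 and with an estimated correlation, Benjamini-Hochberg adjusted over the 35 lists. Camera compares a list with all other genes. Fry, which asks whether a list's genes move on balance one way, and medians of 10000 random lists matched on mean signal were run beside it. Fry called 1 list, mitosis, for movement in one direction (adjusted p = 0.019), and 16 for change in either direction.

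The named genes were the 8 largest increases and the 8 largest decreases among called genes with non-overlapping groups, up to 4 called members of each list with the smallest adjusted p, and a short set named in any case: Ccnb1, Cdk1, Mki67, Ccnd1, Ccna2, Pcna, Cdkn1a, Foxm1, Alb, Cyp7a1, Cyp2e1, Glul, Saa1, Afp, Hgf, Myc, Hnf4a, Per1 and Dbp. Predicted genes and clone names were left out of the largest changes. Genes outside this rule are marked where they appear.

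The code was tested on simulated data for 27022 probe sets, 200 of them changed. With variances drawn from the fitted prior, it called 156, of which 7 were false. Changes of 2-fold were called in 36% of 50 probe sets, 4-fold in 72%, 8-fold in 92% and 16-fold in 98%. With each probe set's own fitted variance taken as true, 23 of 199 calls were false, above the nominal 5%, so the error rate depends on how well the prior describes the true spread. The setting with fitted variances was the first one tried, and its first run gave a still larger share of false calls; the setting with drawn variances was made the first of the pair only after that result was seen. With no change simulated, limma called 0 probe sets, and camera and fry called 0 lists. Each simulated probe set was drawn independently, without correlation between genes. The 0 lists therefore do not show how often camera with the preset correlation calls lists of correlated genes. A list shifted by 1 on the log2 scale was called by camera with the preset correlation (adjusted p = 1.3e-51) and not with an estimated one (adjusted p = 0.0952).

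The alternatives were quantile normalization, median centring, no offset, an offset at the 40th percentile, no filter, a filter at the 60th percentile, eBayes without trend, robust eBayes, the replicate number as a block, leaving out probe sets that may match several transcripts, the mean of a gene's probe sets, and leaving out each array in turn. In the last of these the lone array of a group was assumed to vary like the other group. Signals floored at the control level, and list counts without hepatectomy replicate 1, were added after seeing the data. Tables were prepared with Python 3.11.15 and pandas 2.3.3. The result of 1 of the gene families looked at after the fixed lists is not reported here.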

Results

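RNA from liver of C57BL/6J mice was measured on Affymetrix expression arrays 48 h after surgery. There were 2 arrays from sham-operated mice and 2 from mice after partial hepatectomy, an operation that removes part of the liver and is followed by regrowth of the remainder. Across the 27022 probe sets tested, the median absolute log2 difference was 0.234 between the 2 sham arrays and 0.273 between the 2 hepatectomy arrays. Between a sham and a hepatectomy array it lay between 0.299 and 0.344. The number of arrays limits the precision of every value: the median standard error of a called gene was 0.257 on the log2 scale.

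The comparison asked which liver transcripts differ 48 h after partial hepatectomy from those 48 h after a sham operation. Transcripts of DNA replication and mitosis rose together: 34 of 45 measured replication genes and 53 of 60 measured mitosis genes were higher, and none of either list was lower. The acute phase gene Lcn2, which encodes an iron-siderophore binding protein, rose from a signal of 368 ± 166 to 13572 ± 2424 (SD, n = 2 arrays per group). The bile acid enzymes Cyp8b1 and Cyp7a1 fell the other way, from 4796 ± 3289 to 155 ± 41.7 and from 2438 ± 958 to 146 ± 71.3. Of 30 measured genes of fatty acid and triglyceride synthesis 7 fell, among them Lpin1 and Srebf1, and 2 rose. Of 30 stellate cell and extracellular matrix genes 11 rose, among them Col1a1, and 1 fell.

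By limma with Benjamini-Hochberg adjustment, 916 of 27022 probe sets changed, 679 upward and 237 downward. Counted over genes, 586 of 12560 changed, 449 upward and 137 downward, and 500 of them by at least 2-fold (406 upward, 94 downward). Of the 449 genes that rose, 87 were in the replication or mitosis lists. Without hepatectomy replicate 1, an array with adrenal and fat transcripts described further on, 625 genes changed. The count depended on the other arrays and on the settings: 232 genes without sham replicate 1, 320 without sham replicate 2, 1250 without hepatectomy replicate 2, 218 without the filter on dim probe sets and 173 without a mean-variance trend. The upward share of probe sets was 74.1%, and 63.3% after centring each array on its median, which moved the median log2 fold change of all genes from 0.025 to -0.084.

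The 8 largest increases among genes chosen by the fixed rule were those of Lcn2, Fignl1, Uhrf1, Hmmr, Timp1, Mcm5, Prc1 and Cdc6. Lcn2 rose by a log2 fold change of 5.23 ± 0.29 (SE; adjusted p = 0.000434). Fignl1, which encodes an ATPase of homologous recombination, rose by 5.16 ± 0.49 (adjusted p = 0.0015). Uhrf1, a partner of the maintenance DNA methyltransferase, rose by 4.93 ± 0.42 (adjusted p = 0.001). Timp1, an inhibitor of matrix metalloproteinases, lay under the level of the bacterial control probe sets in both sham arrays and rose at least 19.9-fold (adjusted p = 0.00325; 12.3-fold without hepatectomy replicate 1 and 32.0-fold without replicate 2). The 8 largest decreases were those of Cyp8b1, Car1, Cyp7a1, Cnmd, Rgs16, Slc13a2, Ces2b and Lpin1. Rgs16, a regulator of G protein signalling, fell by 3.21 ± 0.35 (adjusted p = 0.00287), and Cnmd, which encodes chondromodulin, fell by 3.59 ± 0.62 (adjusted p = 0.0205). Slc13a2, a dicarboxylate transporter, fell by 3.01 ± 0.34 (adjusted p = 0.00306), and Ces2b, a carboxylesterase, fell by 2.88 ± 0.55 (adjusted p = 0.0313). Without sham replicate 1, Cnmd (adjusted p = 0.131) and Slc13a2 (adjusted p = 0.0502) lost their calls; without sham replicate 2, Cnmd (0.0728) and Ces2b (0.137) did.

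**Figure D1:**
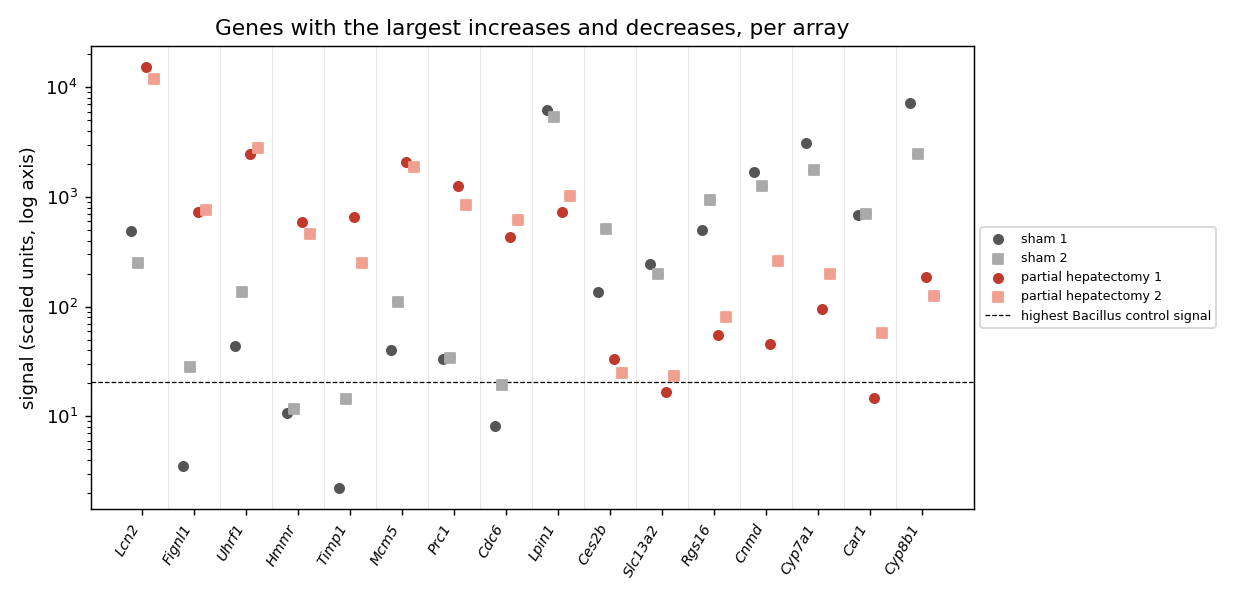
Signal of the 16 genes with the largest increases and decreases on each of the 4 arrays, on a log axis in the authors' scaled units; circles and squares mark replicates 1 and 2, and the dashed line marks the highest signal of the Bacillus control probe sets, 20.4. Lcn2 lay at 485 and 251 in the sham arrays and at 15286 and 11858 in the hepatectomy arrays, and Cyp7a1 and Cyp8b1 were lower in both hepatectomy arrays.

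In the DNA replication list, 34 of 45 measured genes rose, 39 when adjusted over the list alone, where 1 was lower. The 6 subunits of the MCM helicase, which unwinds DNA at replication forks, all rose: Mcm5 by 4.71 ± 0.39 (SE; adjusted p = 0.000925), Mcm6 by 3.72 ± 0.26, Mcm2 by 3.47, Mcm3 by 3.40, Mcm4 by 2.79 ± 0.21 and Mcm7 by 2.19 ± 0.16. Mcm2 and Mcm3 were named after their values were seen. Prim1, the catalytic subunit of DNA primase, rose by 2.88 ± 0.18 (adjusted p = 0.000576). Cdc6, which loads the helicase, was under the control level in both sham arrays and rose at least 25.2-fold (adjusted p = 0.000835). Pcna, the sliding clamp of DNA polymerase, rose by 1.05 ± 0.15 from a sham signal of 2620 ± 430 (adjusted p = 0.00985). The median over the list was 1.66, and camera gave an adjusted p = 3.58e-32 with the preset correlation and an adjusted p = 0.464 with an estimated correlation. Of 21 measured genes of deoxynucleotide synthesis, 5 rose, 6 when adjusted over the list alone, and none fell. These were both subunits of ribonucleotide reductase, Rrm1 (2.41 ± 0.26, adjusted p = 0.00258) and Rrm2 (1.34 ± 0.13, adjusted p = 0.00195), with Dut (1.74 ± 0.19), Dtymk (0.95 ± 0.16) and, named after its value was seen, Mthfd2 (2.25). Rrm2 had a value of 2.56 without probe sets that may match several transcripts. Dtymk lost its call without sham replicate 1 (adjusted p = 0.128) and without sham replicate 2 (adjusted p = 0.0633). The median of that list was 0.10 and its camera adjusted p was 0.0549. Camera called it without hepatectomy replicate 1 (median 0.25, adjusted p = 0.00285) and without sham replicate 2 (median 0.24, adjusted p = 0.0228). Over all 4 arrays it gave an adjusted p = 0.499 with an estimated correlation.

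In the mitosis list, 53 of 60 measured genes rose, 57 when adjusted over the list alone, and none fell. Birc5, a subunit of the chromosomal passenger complex, rose from a signal of 202 ± 8.9 to 2736 ± 12.7 (log2 fold change 3.71 ± 0.18, adjusted p = 0.000224). Prc1, which bundles microtubules of the central spindle, rose by 4.62 ± 0.29 (adjusted p = 0.000547), and Cdca3 rose by 3.57 ± 0.24 (adjusted p = 0.000576). Cdk1, the kinase that drives entry into mitosis, rose by 3.08 ± 0.22 (adjusted p = 0.000719), and the proliferation marker Mki67 rose by 3.06 ± 0.25 (adjusted p = 0.000921). Hmmr was under the control level in both sham arrays and rose at least 25.5-fold (adjusted p = 0.000576); without hepatectomy replicate 1 another probe set stood for it and was not called (1.56, adjusted p = 0.0731), and without hepatectomy replicate 2 another stood for it with a value of 2.26. The median log2 fold change was 2.71, or 2.65 with 12 genes that were under the control level in both sham arrays set to their lower bounds. Camera gave an adjusted p = 3.11e-51 with the preset correlation and an adjusted p = 0.295 with an estimated correlation. Without hepatectomy replicate 1, 34 of 45 replication genes and 48 of 56 mitosis genes rose.

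Of 26 measured regulators of G1 and S phase, 7 rose, 16 when adjusted over the list alone, and none fell. Ccna2, the cyclin A of dividing somatic cells, rose by 3.44 ± 0.26 (SE; adjusted p = 0.000722), and Ccnd1, the cyclin of G1 progression, rose by 1.80 ± 0.20 from a sham signal of 1696 ± 513 (adjusted p = 0.00328). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 3.07 ± 0.28 (adjusted p = 0.00138), and Rbl1, which encodes the pocket protein p107, rose by 2.44 ± 0.23 (adjusted p = 0.00145). The list's median was 0.65, with a camera adjusted p = 1.72e-08 and an adjusted p = 0.464 with an estimated correlation. Foxm1, a transcription factor of mitotic genes, had a log2 fold change of 1.21 ± 0.34 and did not pass (adjusted p = 0.107), though it did with the mean of a gene's probe sets (1.79, adjusted p = 0.0366), and Ccnb1 had no probe set of its own. Cdkn1a was also the 1 of 18 measured p53 targets that rose; 4 did when adjusted over the list alone, and camera did not call the list (adjusted p = 0.0527), though it did without sham replicate 1 (adjusted p = 0.0231) and without hepatectomy replicate 2 (adjusted p = 0.0199). With an estimated correlation the 4 arrays gave an adjusted p = 0.499. None of 25 immediate early and growth factor signalling genes passed, 5 when adjusted over the list alone. Myc differed by -1.09 ± 0.67 (adjusted p = 0.477), or by -2.29 and called without sham replicate 2. Hgf differed by 0.68 ± 0.32 (adjusted p = 0.339) in its probe set with the highest mean, while 1 of its 3 tested probe sets was called higher. The median of these 25 genes was 0.62, with a camera adjusted p = 0.00811 and an adjusted p = 0.499 with an estimated correlation. Without hepatectomy replicate 1 the median was 0.23 and camera did not call the list (adjusted p = 0.0912), nor did it without sham replicate 2 (adjusted p = 0.0794). Of 31 ribosome biogenesis genes 1 rose, 2 when adjusted over the list alone: Nop58, a core protein of box C/D particles (1.07 ± 0.20, adjusted p = 0.0295), which lost its call without sham replicate 1 (adjusted p = 0.25) and without sham replicate 2 (adjusted p = 0.078). Camera did not call that list (median 0.10, adjusted p = 0.0643), though it did without hepatectomy replicate 1 (median 0.27, adjusted p = 0.00558) and without sham replicate 2 (median 0.31, adjusted p = 0.02). With an estimated correlation the 4 arrays gave an adjusted p = 0.631.

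Bile acid genes held 2 of the 8 largest decreases. Cyp8b1, the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell by 4.71 ± 0.44 (SE; adjusted p = 0.00146), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 4.01 ± 0.37 (adjusted p = 0.00145). Cyp27a1, of the alternative pathway, fell by 0.92 ± 0.14 (adjusted p = 0.0123), as did Abcg8, a sterol exporter named after its value was seen (-1.23). Slc51b, a subunit of the basolateral bile acid exporter, rose by 2.78 ± 0.55 (adjusted p = 0.0354). Its signal was 1717 in hepatectomy replicate 1 and 481 in replicate 2. The call of Slc51b was lost with robust eBayes (adjusted p = 0.178), without the filter (0.148), without trend (0.186) and with the mean of a gene's probe sets (0.059). In all, 4 of 27 measured genes fell and 1 rose, against 10 and 2 when adjusted over the list alone. The median was -0.20, and -0.42 without sham replicate 2. Over all 4 arrays camera gave an adjusted p = 0.000162 and an adjusted p = 0.489 with an estimated correlation. Without sham replicate 1, Cyp27a1 (adjusted p = 0.0789) and Slc51b (adjusted p = 0.209) lost their calls, and Slc51b did so without sham replicate 2 as well (adjusted p = 0.0624).

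Of 47 measured cytochrome P450 and phase I genes, 1 fell and 1 rose, against 4 and 1 when adjusted over the list alone: Cyp2d22 fell by 0.92 ± 0.13 (SE; adjusted p = 0.0102) and Cyp2c38 rose by 1.64 ± 0.30 (adjusted p = 0.0281). The median of the list was -0.18 with 34 of 47 values negative (camera adjusted p = 3.81e-05; adjusted p = 0.499 with an estimated correlation). It was -0.305 without sham replicate 2 and also without hepatectomy replicate 2. Cyp2e1, an abundant P450 of the pericentral zone, differed by -0.21 ± 0.10 (adjusted p = 0.381). Of 32 phase II conjugation genes, 4 fell and 2 rose, against 5 and 2 when adjusted over the list alone. The glucuronosyltransferases Ugt2a3 (-0.76 ± 0.13), Ugt2b1 (-0.70 ± 0.13) and Ugt3a1 (-1.05 ± 0.20) fell with Sult1c2 (-2.24), and the glutathione transferase Gstm2 (0.98 ± 0.19) rose with Nnmt (0.57); Sult1c2 and Nnmt were named after their values were seen. The phase II median was -0.18 (camera adjusted p = 0.00102; adjusted p = 0.499 with an estimated correlation), and camera did not call the list without sham replicate 1 (adjusted p = 0.0947). Without sham replicate 1 or without sham replicate 2, the calls of Cyp2d22, Cyp2c38, Ugt2a3, Ugt2b1 and Ugt3a1 were lost (adjusted p from 0.0571 to 0.173). Gstm2 lost its call without sham replicate 2 (adjusted p = 0.123) and without hepatectomy replicate 1 (adjusted p = 0.0558), and Ugt2b1 without the latter (adjusted p = 0.0846).

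Genes of fatty acid and triglyceride synthesis fell more often than they rose: 7 of 30 measured were lower and 2 higher, against 12 and 3 when adjusted over the list alone. Lpin1, a phosphatidate phosphatase, fell from a signal of 5746 ± 548 to 874 ± 196 (log2 fold change -2.72 ± 0.19, adjusted p = 0.000657). Srebf1, the transcription factor of lipogenic genes, fell from 5349 ± 563 to 2048 ± 546 (adjusted p = 0.00868), and Acss2, which makes acetyl-CoA from acetate, fell by 1.23 ± 0.14 (adjusted p = 0.00315). Fabp4, a fatty acid binding protein abundant in fat cells, rose by 1.53 ± 0.24 (adjusted p = 0.0157). Its signal was 4391 in hepatectomy replicate 1 and 2592 in replicate 2, and the fat genes Adipoq and Retn also stood higher in replicate 1 (574 and 284 against 56.3 and 13.8). Without replicate 1, 7 of the 30 were lower and 1 higher. The list's median was -0.29 (camera adjusted p = 4.39e-05; adjusted p = 0.489 with an estimated correlation), and -0.18 without sham replicate 1. Of 34 genes of fatty acid oxidation and ketogenesis, 5 rose and none fell, against 8 and 1 when adjusted over the list alone. They were the thioesterases Acot3 (2.50 ± 0.23, adjusted p = 0.00145), Acot2 (2.01 ± 0.30, adjusted p = 0.0114) and, named after its value was seen, Acot1 (1.11), the carnitine acetyltransferase Crat (1.50 ± 0.20, adjusted p = 0.00815) and the hormone gene Fgf21, which was under the control level in both sham arrays and rose at least 10.2-fold (adjusted p = 0.0155; 5.7-fold without hepatectomy replicate 1 and 18.3-fold without replicate 2). Crat was called in 1 of its 3 tested probe sets, and the mean of its probe sets gave 1.01 without a call (adjusted p = 0.0745). The members that rose hold no enzyme of the beta-oxidation cycle itself. The median of that list was 0.09, turning to -0.02 after median centring, with a camera adjusted p = 0.0386 and an adjusted p = 0.499 with an estimated correlation. It was 0.14 without hepatectomy replicate 1, 0.19 without sham replicate 1 and 0.06 without sham replicate 2. Camera did not call the list without sham replicate 2 (adjusted p = 0.363) or without hepatectomy replicate 2 (adjusted p = 0.115). None of 20 genes of cholesterol synthesis and uptake passed, and none did when adjusted over the list alone; their median was -0.13 (camera adjusted p = 0.0386; adjusted p = 0.631 with an estimated correlation). Camera did not call them without hepatectomy replicate 1 (median -0.055, adjusted p = 0.675) or without sham replicate 1 (median 0.045, adjusted p = 0.879). The median was -0.26 without sham replicate 2 and -0.25 without hepatectomy replicate 2. Calls lost without sham replicate 1 were those of Acot2 (adjusted p = 0.053), Crat (0.0704) and Fabp4 (0.102), and without sham replicate 2 those of Acot2 (0.0555), Fgf21 (0.0737) and Srebf1 (0.0576).

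Of 25 genes of glucose and glycogen metabolism, 3 rose and 2 fell, against 3 and 7 when adjusted over the list alone. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 2.17 ± 0.27 (SE; adjusted p = 0.00537), and Pklr, the liver pyruvate kinase, fell by 1.11 ± 0.17 (adjusted p = 0.0111). Pkm, the pyruvate kinase of most other tissues, rose by 1.58 ± 0.28 (adjusted p = 0.0218), Pygl, the liver glycogen phosphorylase, fell by 0.80 ± 0.13 (adjusted p = 0.0168), and Ppp1r3c, named after its value was seen, rose by 1.01. The list as a whole had a median of -0.02 (camera adjusted p = 0.0726), and -0.14 without sham replicate 2, where camera called it (adjusted p = 0.0242). Its adjusted p over all 4 arrays was 0.489 with an estimated correlation. Of 40 genes of the urea cycle and amino acid catabolism, 3 fell, also when adjusted over the list alone, and none rose: Csad, of taurine synthesis (-2.43 ± 0.21, adjusted p = 0.00114), Afmid, of tryptophan breakdown (-2.00 ± 0.28, adjusted p = 0.00868), and Prodh, proline dehydrogenase (-1.11 ± 0.17, adjusted p = 0.0144). Their list had a median of -0.12 (camera adjusted p = 0.000868; adjusted p = 0.551 with an estimated correlation), and -0.23 without sham replicate 2. Without sham replicate 1 the median was -0.03 and camera did not call it (adjusted p = 0.21). None of 39 oxidative phosphorylation genes passed, and none did when adjusted over the list alone, while 36 had values below 0 and the median was -0.15 (camera adjusted p = 1.99e-05; adjusted p = 0.514 with an estimated correlation), or -0.24 without sham replicate 2. Without sham replicate 1, Pklr (adjusted p = 0.0785), Pkm (0.151), Pygl (0.1) and Prodh (0.127) lost their calls, as did Pkm without sham replicate 2 (adjusted p = 0.0808).

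Of 35 measured acute phase genes 9 rose and none fell, against 17 and 1 when adjusted over the list alone. Besides Lcn2, the serum amyloid genes Saa2 (1.79 ± 0.13 SE, adjusted p = 0.000722) and Saa1 (0.78 ± 0.12, adjusted p = 0.0144), the orosomucoid gene Orm2 (2.19 ± 0.21, adjusted p = 0.0018) and Apcs, which encodes serum amyloid P (1.03 ± 0.11, adjusted p = 0.00287), rose. The median was 0.69 (camera adjusted p = 7.05e-09; adjusted p = 0.499 with an estimated correlation). Without hepatectomy replicate 1 it was 0.26, with 9 of 35 higher (camera adjusted p = 1.52e-06). Saa1 had a value of 1.36 without probe sets that may match several transcripts. Median centring ended the call of Saa1 (adjusted p = 0.064). Of 49 secreted plasma protein genes 1 rose, also when adjusted over the list alone, and none fell. That gene was Apoa4, an apolipoprotein, which went from 1828 ± 8.8 to 11257 ± 207 (2.62 ± 0.12, adjusted p = 0.000218). Albumin mRNA (Alb) stood at 16538 ± 2040 in sham and 15536 ± 802 in hepatectomy arrays (adjusted p = 0.777). The list's median was -0.07 and camera did not call it (adjusted p = 0.0712), though it did without sham replicate 2 (median -0.15, adjusted p = 3.41e-05) and without hepatectomy replicate 2 (adjusted p = 0.0245). With an estimated correlation all 4 arrays gave an adjusted p = 0.702.

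Of 22 hepatocyte transcription factors 1 rose and none fell, against 1 and 1 when adjusted over the list alone: Atf5 (0.98 ± 0.20 SE, adjusted p = 0.0428). It lost its call without sham replicate 1, with a value of 0.66. The call was also lost under median centring (adjusted p = 0.0508), with the mean of a gene's probe sets (0.0639) and without the filter (0.158). Hnf4a differed by -0.13 ± 0.10 (adjusted p = 0.621), and camera did not call the list (median -0.01, adjusted p = 0.273). Among 19 pericentral markers 1 fell, Cyp27a1, and 4 fell and 1 rose when adjusted over the list alone. Glul, which encodes glutamine synthetase, differed by -0.08 ± 0.12 (adjusted p = 0.789). Among 18 periportal markers, Pigr, the receptor that carries IgA into bile, fell (-0.80 ± 0.11, adjusted p = 0.00947), Etnppl fell (-0.88 ± 0.18, adjusted p = 0.0419) and Apoc2 rose (0.55 ± 0.10, adjusted p = 0.0254); adjusted over the list alone, 3 fell and 1 rose. Camera called neither zonal list (adjusted p = 0.0915 for pericentral genes with a median of -0.09, and 0.0759 for periportal genes with a median of -0.03). It called the pericentral list without hepatectomy replicate 2 (adjusted p = 0.0301). It called the periportal list without hepatectomy replicate 1 (median -0.11, adjusted p = 0.0395) and without sham replicate 2 (median -0.18, adjusted p = 0.0049). With an estimated correlation the adjusted p over all 4 arrays was 0.499 for the pericentral and 0.528 for the periportal list. Etnppl (adjusted p = 0.297) and Pigr (0.0587) lost their calls without sham replicate 1, and Apoc2 without sham replicate 2 (0.0627) and without hepatectomy replicate 1 (0.12). Of 22 genes of endoplasmic reticulum stress 1 rose and none fell, against 1 and 2 when adjusted over the list alone: Asns, asparagine synthetase (1.97 ± 0.32, adjusted p = 0.0175; 0.125 without sham replicate 1). The median of those 22 genes was -0.01 (camera adjusted p = 0.772). None of 22 interferon response genes passed, nor when adjusted over the list alone; their median was 0.00 and their mean -0.07 (camera adjusted p = 0.289, direction down).

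Among markers of myeloid cells, 3 of 11 measured monocyte and neutrophil genes rose, 8 when adjusted over the list alone, and none fell. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils and monocytes, rose by 3.92 ± 0.51 (SE; adjusted p = 0.00636) and 3.84 ± 0.36 (adjusted p = 0.0015), and Prtn3, a neutrophil granule protease, rose by 4.44 ± 0.54 (adjusted p = 0.00425). S100a8 lost its call with robust eBayes (adjusted p = 0.0978), without the filter (0.0514) and without trend (0.0973), and Prtn3 without trend (0.0714). The list's median was 2.82, or 2.98 with 1 gene set to its lower bound (camera adjusted p = 2.56e-06; adjusted p = 0.489 with an estimated correlation). Its genes stood higher in hepatectomy replicate 1, by a median of 1.38 over replicate 2, and without that replicate the list's median was 1.30, with 3 of 11 genes higher. Among 25 Kupffer cell and macrophage markers, 2 rose and 2 fell, against 3 and 2 when adjusted over the list alone. The scavenger receptor gene Marco rose by 3.45 ± 0.32 (adjusted p = 0.00145) and Trem2, a lipid-sensing receptor, rose at least 4.5-fold from signals under the control level (adjusted p = 0.00761). Cd74, the invariant chain of MHC class II, fell by 1.57 ± 0.21 (adjusted p = 0.00691), and Csf1r, the receptor of macrophage colony-stimulating factor, fell by 0.70 ± 0.13 (adjusted p = 0.0317). The Kupffer list had a median of -0.11, a mean of 0.17 and a camera adjusted p = 0.674 in the downward direction. Csf1r lost its call without sham replicate 1 (adjusted p = 0.217), without sham replicate 2 (0.14) and without hepatectomy replicate 1 (0.0609).

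Lymphocyte markers had lower values, 13 of 14 below 0 with a median of -0.70, but 1 gene fell, Gzma (-1.46 ± 0.30 SE, adjusted p = 0.041), a granzyme of cytotoxic cells; 3 fell when adjusted over the list alone. Camera gave an adjusted p = 0.000334 for this list and an adjusted p = 0.464 with an estimated correlation. With the filter at the 60th percentile the median was -0.10 and camera did not call it (adjusted p = 0.682). Gzma lost its call without sham replicate 1 (adjusted p = 0.286) and without sham replicate 2 (0.199). Of 5 measured erythroid markers 2 fell, 3 when adjusted over the list alone: Car1, a carbonic anhydrase of red cells (-4.14 ± 0.46, adjusted p = 0.00293), and Klf1, a transcription factor of erythroid precursors (-1.82 ± 0.27, adjusted p = 0.0108; 0.121 without sham replicate 1). The erythroid median was -0.96 (camera adjusted p = 0.00496; adjusted p = 0.489 with an estimated correlation). None of 24 endothelial markers passed, nor when adjusted over the list alone; their median was -0.17 (camera adjusted p = 0.0323; adjusted p = 0.526 with an estimated correlation). Camera did not call them without hepatectomy replicate 1 (median -0.01, adjusted p = 0.183) or without sham replicate 2 (adjusted p = 0.125).

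Of 30 measured stellate cell and extracellular matrix genes 11 rose and 1 fell, against 16 and 1 when adjusted over the list alone. Col1a1, a chain of type I collagen, rose from 268 ± 132 to 1664 ± 588 (log2 fold change 2.64 ± 0.36, adjusted p = 0.00827). Acta2, smooth muscle actin and a marker of activated stellate cells, rose by 1.61 ± 0.22 (adjusted p = 0.00834), and Tagln, an actin-binding protein, rose by 1.49 ± 0.21 (adjusted p = 0.00827). The gene that fell was Ecm1, named after its value was seen (-0.98). The median was 0.90 (camera adjusted p = 5.62e-06; adjusted p = 0.499 with an estimated correlation). Without hepatectomy replicate 1 it was 0.65, with 10 of 28 higher (camera adjusted p = 1.39e-05). Acta2 (adjusted p = 0.0734) and Tagln (0.0818) lost their calls without sham replicate 1. Of 17 cholangiocyte and progenitor markers 3 rose, 7 when adjusted over the list alone, and none fell. These were Anxa2 (2.02 ± 0.31, adjusted p = 0.0132), the keratin gene Krt18, which hepatocytes also express (0.62 ± 0.11, adjusted p = 0.0252), and Tnfrsf12a, the receptor of TWEAK (2.19 ± 0.40, adjusted p = 0.0269). Afp, the fetal serum protein alpha-fetoprotein, had a log2 fold change of 1.36 ± 0.32 (adjusted p = 0.0636). It passed with robust eBayes (adjusted p = 0.0431) and without hepatectomy replicate 2 (1.47, adjusted p = 0.0438). The list's median was 0.77 (camera adjusted p = 2e-05; adjusted p = 0.499 with an estimated correlation); 17 of its 17 genes stood higher in hepatectomy replicate 1 than in replicate 2, and the median was 0.53 without replicate 1, with 3 of 16 higher, and 1.26 without replicate 2. Anxa2 (adjusted p = 0.0803), Krt18 (0.0931) and Tnfrsf12a (0.162) lost their calls without sham replicate 1, as did Anxa2 without sham replicate 2 (0.0534) and Krt18 without hepatectomy replicate 1 (0.108).

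**Figure D2:**
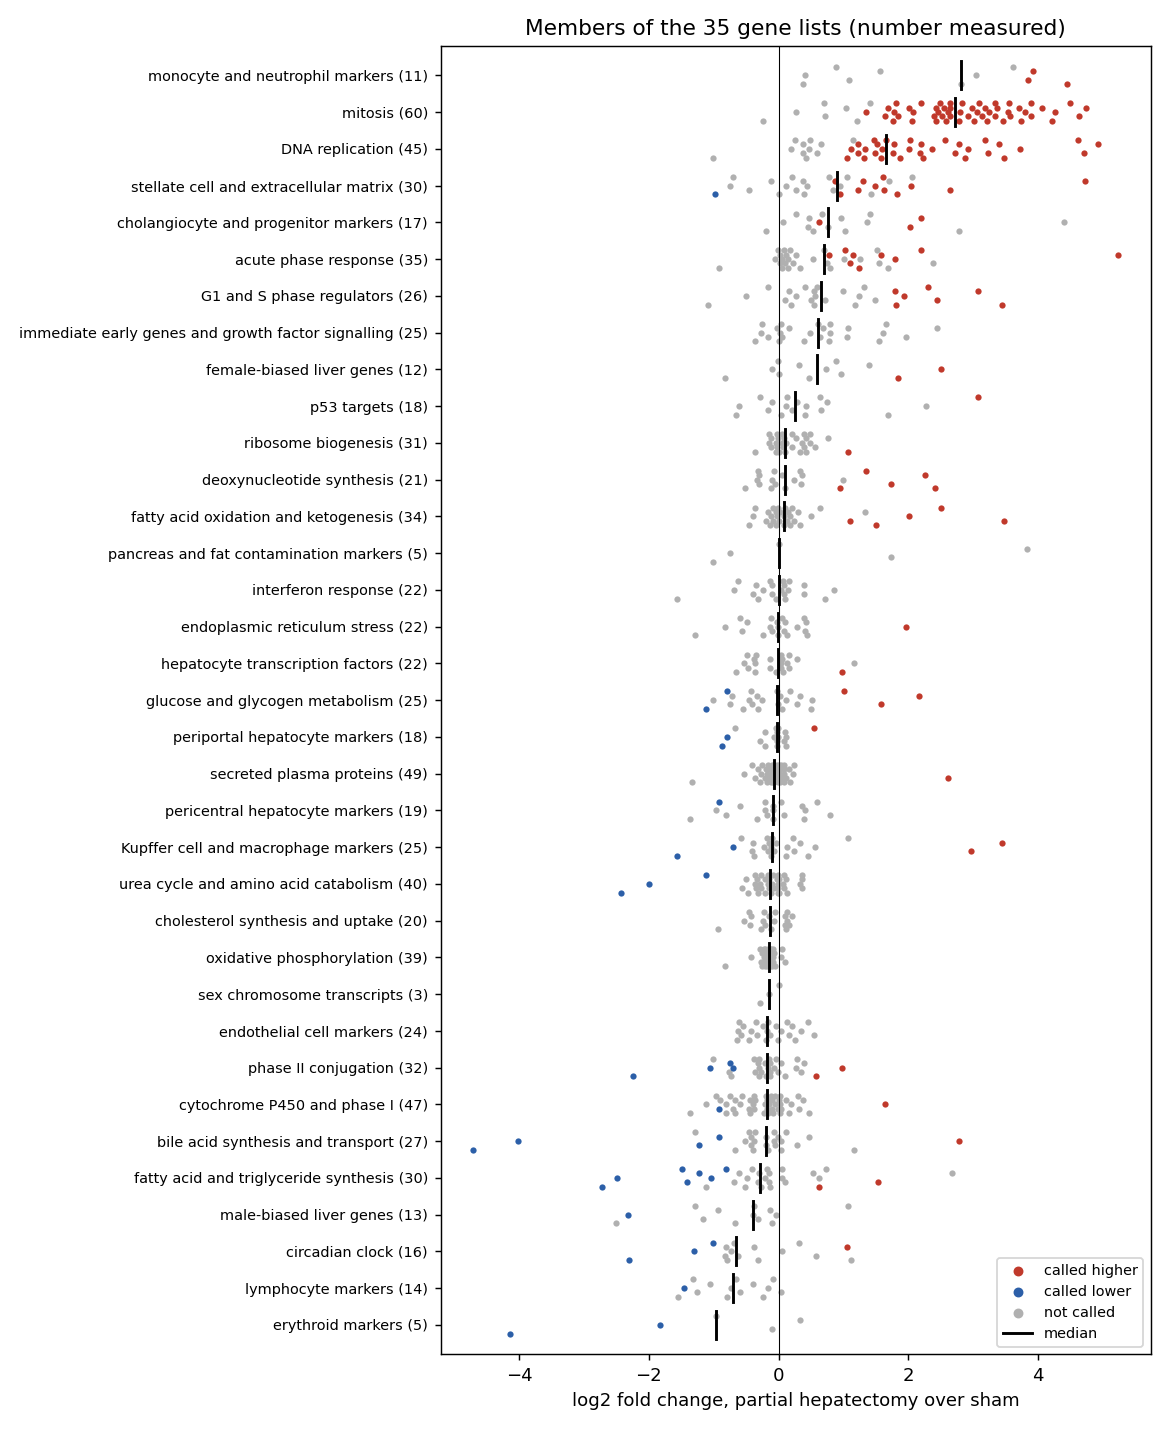
Log2 fold change (partial hepatectomy over sham) of each measured member of the 35 gene lists, with lists ordered by their median (black bar) and the number measured in parentheses; red and blue points are genes called higher and lower, and grey points were not called. Mitosis (53 of 60) and DNA replication (34 of 45) held the most genes called higher, and the lists of hepatocyte metabolism lay near 0.

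Genes of the circadian clock were among those that fell. Dbp, a transcription factor driven by the clock, fell by 1.30 ± 0.20 (SE; adjusted p = 0.0143), Per3 by 1.01 ± 0.18 (adjusted p = 0.0248) and Ciart, a repressor of the clock, by 2.30 ± 0.48 (adjusted p = 0.0444), with a value of -1.47 without hepatectomy replicate 1. Nfil3, a repressor that acts on the targets of Dbp, rose by 1.06 ± 0.22 (adjusted p = 0.0437). Of 16 measured clock genes 3 fell and 1 rose, against 7 and 2 when adjusted over the list alone, and Per1 differed by -0.73 ± 0.24 (adjusted p = 0.173). The median was -0.66 (camera adjusted p = 0.00126; adjusted p = 0.489 with an estimated correlation), and -0.42 without hepatectomy replicate 1. All 4 calls were lost without sham replicate 1 (adjusted p from 0.0582 to 0.225) and without sham replicate 2 (from 0.0899 to 0.232), and that of Nfil3 also without hepatectomy replicate 1 (0.0727) and after quantile normalization (0.0516) or median centring (0.0573).

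Genes higher in male than in female liver had lower values, 12 of 13 below 0 with a median of -0.40, and 1 fell, Ugt2b38 (-2.33 ± 0.43 SE, adjusted p = 0.0271; 0.0964 without sham replicate 2). When adjusted over the list alone, 6 fell (camera adjusted p = 0.000113; adjusted p = 0.464 with an estimated correlation). Of 12 genes higher in female liver 2 rose, also when adjusted over the list alone, and none fell: the thioesterase gene Acot3 and Cux2, a transcription factor of female liver (1.84 ± 0.36, adjusted p = 0.0335). Cux2 lost its call without each array in turn (adjusted p from 0.127 to 0.978). Another of its probe sets stood for it when a hepatectomy array was left out, with a value of 0.05 without replicate 1 and 0.83 without replicate 2, while the first probe set lay 2.33 above sham in replicate 1 and 1.35 above it in replicate 2. The female list had a median of 0.60 (camera adjusted p = 0.0386, or 0.0885 without hepatectomy replicate 1 and 0.0689 without sham replicate 2; adjusted p = 0.489 with an estimated correlation). None of 3 Y-linked genes passed, nor when adjusted over the list alone (median -0.15, camera adjusted p = 0.289), and Eif2s3y, which lies on the Y chromosome, had signals of 4151 in sham and 3387 in hepatectomy arrays.

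Transcripts of the adrenal gland stood out in hepatectomy replicate 1 alone. Hsd3b1 and Cyp11a1, enzymes of steroid synthesis, had signals of 7227 and 2322 in that array, and at most 24.4 and 13.7 in the other 3. Chgb, of adrenal medulla granules, had a signal of 2438 there and at most 24.8 elsewhere. Over 29 adrenal cortex and medulla markers the median log2 difference between hepatectomy replicates 1 and 2 was 2.22, and the fat genes Adipoq and Retn stood at 574 and 284 against 56.3 and 13.8. Of the 29 markers, 19 had not been looked at when the list was written, and the genes named here were chosen after their values were seen. Of the 5 measured genes in the fixed list of pancreas and fat markers none passed, while 1 was higher and 1 lower when adjusted over the list alone; the median was 0.01, the mean 0.76 and camera did not call it (adjusted p = 0.826, direction down).

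**Figure D3:**
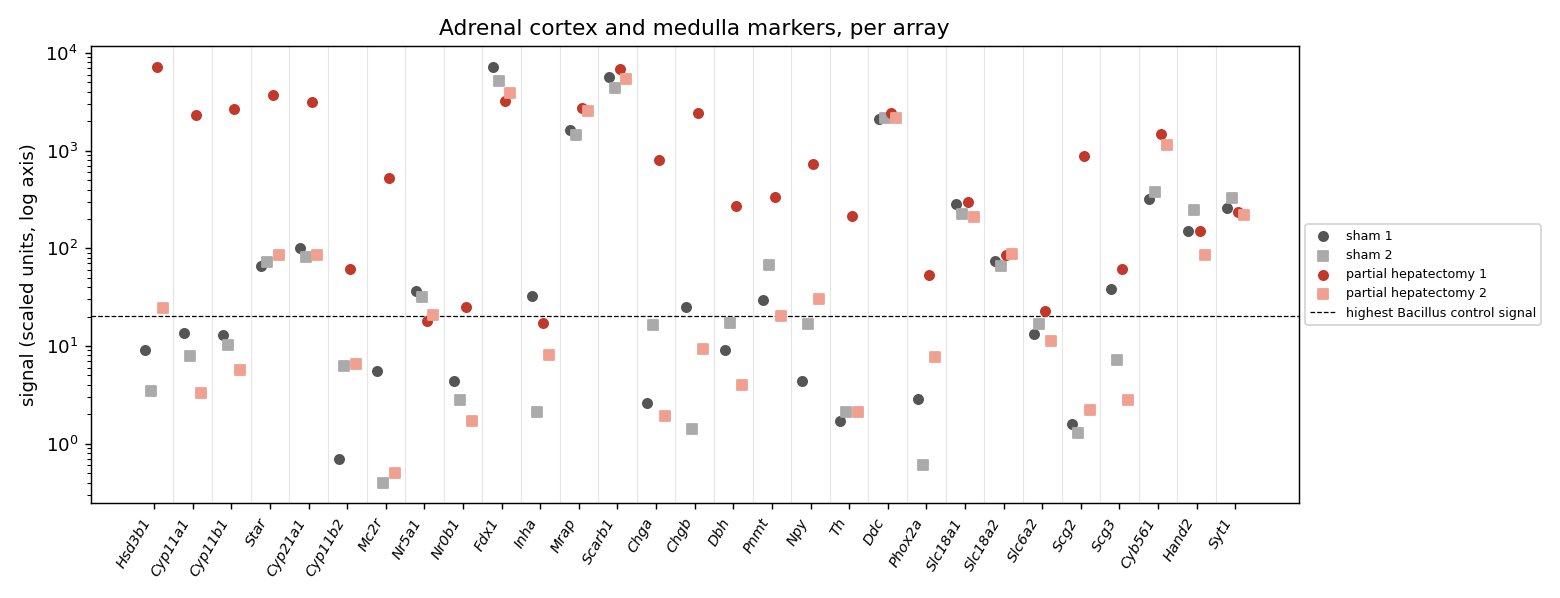
Signal of 29 adrenal cortex and medulla markers on each of the 4 arrays, on a log axis in the authors' scaled units; circles and squares mark replicates 1 and 2, and the dashed line marks the highest signal of the Bacillus control probe sets. Hsd3b1 reached 7227 in hepatectomy replicate 1 and at most 24.4 in the other 3 arrays, while Scarb1 lay between 4368 and 6874 on all 4 arrays.

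With its preset correlation camera called 22 of the 35 lists, 10 upward and 12 downward, and with an estimated correlation it called 0 (adjusted p from 0.295 to 0.884). In the 2 other ways of splitting the 4 arrays into pairs, the preset correlation called 7 and 11 lists, with 0 changed probe sets by limma in either (572 and 291 at an unadjusted p under 0.05, against 4495 in the real split). Those splits mixed sham and hepatectomy arrays within each group. An effect of the operation therefore widened their spread, and low counts by limma say little. The preset correlation still called lists in both, so its call of a list does not by itself show an effect of the operation.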

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

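Floored signals were an alternative chosen after seeing the data; the others were planned. Changed probe sets, changed genes and genes changed at least 2-fold numbered 916, 586 and 500. They stayed within 1.5 times of these under quantile normalization, median centring, both other offsets, the 60th percentile filter, robust eBayes, floored signals and leaving out probe sets that may match several transcripts. The gene counts did so with the mean of a gene's probe sets as well. Without the filter they were 308, 218 and 214, and without a mean-variance trend 258, 173 and 173. With 1 array left out they ranged from 341 to 2012, from 232 to 1250 and from 225 to 986. The lowest came without sham replicate 1 and the highest without hepatectomy replicate 2; without sham replicate 2 they were 479, 320 and 306. Without hepatectomy replicate 2, the only hepatectomy array left was replicate 1, which held the adrenal and fat transcripts. The cause of these ranges was not tested. With the replicate number as a replicate block they were 1943, 1189 and 840. Nothing in the labels ties replicates of equal number together, and the deviations of same-numbered arrays from their group means correlated at 0.102 across probe sets. Some technical controls were higher in replicate 1 of both groups. Mean signal of the control bioB was 2278.4 and 2047.2 in sham replicates 1 and 2, and 2246.5 and 1993.9 in hepatectomy replicates 1 and 2. The 3' to 5' ratios of beta-actin and Gapdh ran the same way. The 18S rRNA signal did not (1379.1 and 2958.6 in sham, 3408 and 580.6 in hepatectomy arrays). A batch that followed the replicate number therefore remains open. Of 35 lists, camera called 22 with the preset correlation and 0 with an estimated one, and fry called 1.

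Of the 87 called genes that are named, 30 kept their call in every alternative that tested them and none changed direction. Calls were lost by 55 without trend, 40 without the filter, 35 without sham replicate 1, 25 without sham replicate 2, 15 with the mean of a gene's probe sets, 8 without hepatectomy replicate 1, 6 under median centring, 5 with robust eBayes, 1 under quantile normalization and 1 without hepatectomy replicate 2. The 6 lost under median centring were Apoc2, Atf5, Gstm2, Krt18, Nfil3 and Saa1. With the mean of a gene's probe sets, Anxa2 moved from 2.02 to 0.81, Acss2 from -1.23 to -0.65, Per3 from -1.01 to -0.48, Acot2 from 2.01 to 1.17 and Etnppl from -0.88 to -0.52. Without probe sets that may match several transcripts, Rrm2 moved from 1.34 to 2.56 and Saa1 from 0.78 to 1.36; Trem2 moved from 2.97 to 1.91 with the offset at the 40th percentile. Calls were gained by Foxm1 with the mean of a gene's probe sets, Afp with robust eBayes, the replicate block and without hepatectomy replicate 2, and Myc without sham replicate 2. The upward share of probe sets, 74.1%, was 86.4% without the filter, 91.1% without trend and between 63.5% and 87.1% with 1 array left out.

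Medians of 11 lists changed sign in some setting, and those of 24 lists in none. Under median centring they were -0.009 for deoxynucleotide synthesis, -0.009 for ribosome biogenesis, -0.018 for fatty acid oxidation, -0.103 for pancreas and fat markers and -0.104 for the interferon response. Quantile normalization gave 0.014 for glucose metabolism, -0.047 for pancreas and fat markers, -0.037 for the interferon response and 0.031 for endoplasmic reticulum stress. The interferon median was -0.042 with the mean of a gene's probe sets, and that of endoplasmic reticulum stress was 0.051 without probe sets that may match several transcripts. With 1 array left out, medians ranged from -0.261 to 0.045 for cholesterol synthesis, from -0.171 to 0.014 for glucose metabolism, from -0.15 to 0.034 for plasma proteins, from -0.136 to 0.095 for Kupffer cell markers and from -0.395 to 0.167 for pancreas and fat markers. The ranges were -0.187 to 0.058 for the interferon response, -0.035 to 0.017 for endoplasmic reticulum stress and -0.273 to 0.001 for Y-linked genes. Alb, Glul and Myc, none of them called with all 4 arrays, ranged from -0.212 to 0.041, -0.191 to 0.025 and -2.287 to 0.102. Apart from left-out arrays, camera calls ended in at least 1 setting for fatty acid oxidation, cholesterol synthesis, endothelial, lymphocyte and female-biased genes. They appeared for deoxynucleotide synthesis, p53 targets, ribosome biogenesis and plasma proteins. Signal over background limits the folds of the 41 genes that rose from under the control level.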

Other observations

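Outside the 35 fixed lists, 405 further genes changed, 301 upward and 104 downward; the genes and families by symbol described here (10 families were looked at), the tests of clock time, of noise, of induction and of replicate 1 for lipid genes, the count of markers under the control level, the reason for leaving the food explanation open and the test of other splits were chosen after the values were seen. Among them, Chek1, a checkpoint kinase, rose by a log2 fold change of 4.04 ± 0.27 (SE), Exo1 by 3.50 ± 0.36 and Brca1 by 2.92 ± 0.25. Of 19 measured genes named Cenp, which encode centromere and kinetochore proteins, 12 rose and none fell, 5 of the 19 being in a fixed list (Fisher's exact test, two-sided, p = 3.56e-12 for changed genes against all other genes). Of 10 Fanconi anaemia genes 2 rose, Fancb (2.37 ± 0.31) and Fancg (1.25 ± 0.24; Fisher's exact p = 0.0763). Id1, Id2 and Id3, inhibitors of helix-loop-helix transcription factors and targets of BMP signalling, rose by 2.79 ± 0.20, 0.67 ± 0.14 and 1.53 ± 0.22, and Id4 had a value of 0.32 (4 genes; Fisher's exact p = 0.00039). Tpm1, Tpm2 and Tpm4, actin-binding tropomyosins, rose by 1.02 ± 0.17, 1.02 ± 0.22 and 1.23 ± 0.23, and Tpm3 had a value of 0.39 (4 genes; Fisher's exact p = 0.00039). The activin subunit genes Inhbb (2.42 ± 0.41) and Inhbe (1.31 ± 0.25) rose, 2 of 4 measured (Fisher's exact p = 0.0122).

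Among genes that fell, the MHC class II genes H2-Ab1 (-1.94 ± 0.28, adjusted p = 0.0105) and H2-Eb1 (-1.57 ± 0.29, adjusted p = 0.0282) went with the invariant chain Cd74; all 8 measured class II genes had values below 0 with a median of -1.04, though the share of changed genes did not pass (Fisher's exact p = 0.0505). Of 12 carboxylesterases, 2 of them in a fixed list, 3 fell: Ces2b, Ces1e (-1.49 ± 0.27) and Ces2a (-1.03 ± 0.20) (Fisher's exact p = 0.0162). The 4 pyruvate dehydrogenase kinases moved apart. Pdk4, which is in a fixed list, rose (2.17 ± 0.27). Pdk1 (-1.24 ± 0.21) and Pdk2 (-1.04 ± 0.18) fell, and Pdk3 had a value of 0.55 (Fisher's exact p = 0.00039 for the 4 genes). Of 11 acyl-CoA thioesterases 5 rose and 1 fell, Acot6 (2.14 ± 0.26) rising and Acot11 (-1.19 ± 0.23) falling (Fisher's exact p = 3.8e-06). A fixed list held 4 of the 11, and the rises of Acot1, Acot2 and Acot3 were already counted there. The p-values of these families describe groups picked for their changes and are not independent evidence.

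Adrenal transcripts appeared in hepatectomy replicate 1 alone. Over the 19 adrenal markers not looked at before, the median difference from replicate 2 was 0.64 (member SD 2.01). It lay at percentile 99.96 among 10000 random lists matched on signal in the other 3 arrays (highest 0.85). This argues against noise of dim probe sets. Kidney markers (median 0.13, member SD 0.65, 11 genes) argue against kidney tissue. In replicate 2 against sham, the median of the same 19 was -0.24 (member SD 0.66). That value cannot decide about steroid genes induced by hepatectomy, because 11 of the 19 were markers of the medulla. Over all 13 cortex markers, some of them looked at before, the median in replicate 2 against sham was -0.24, with 8 negative. A candidate explanation is adrenal tissue in the piece: the median of 0.64 lay between the bounds set beforehand for and against it, so that test left it open. The 19 also held genes with high signals on every array, sham arrays included. Among them were Fdx1 (3237.1 to 7171.1), Scarb1 (4367.8 to 6874.3), Ddc (2122.4 to 2415.4) and Mrap (1451.2 to 2758). Such genes do not mark adrenal tissue in these arrays, so a median that includes them could not decide whether it was present. Of the 7 of these 19 that were under the control level in the other 3 arrays, 7 were above it in replicate 1, against 18.9% of all such genes, a count chosen after seeing the data. Fat markers not looked at singly before had a median of 1.88 (10 genes), in the direction of fat tissue in the same piece, which would not itself bring steroid enzymes. Cidec and Cidea among them also belonged to the fixed list of fatty acid and triglyceride synthesis. No biological explanation beyond induction was tested.

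Clock output genes had lower values after hepatectomy. Hepatectomy replicate 1 alone does not account for it: in replicate 2 the 10 genes high with Dbp had a median of -0.56 against sham, 9 of them below 0. The 4 genes that run opposite to Dbp stood 1.62 above the 10 in median log2 fold change, but all 14 had been looked at before, so this value decides nothing about a clock time that differed between the groups. The hour of sampling is not given in the sources used here, and a different hour or a shift of the clock after the operation itself may give the same values, so both remain open.

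Of 30 measured genes of fatty acid and triglyceride synthesis, 7 fell after hepatectomy and 2 rose. Replicate 1 alone does not account for the falls, since 7 of the 30 were called lower without it. If less food eaten before sampling were the cause, 12 fasting response genes not looked at singly before could have risen. Several were members of the fixed lists, among them Cpt1a, G6pc and Tat, and Lpin2 belonged to the synthesis list itself. The set was therefore not independent of the list results. The median of the 12 was 0.09 with members between -0.75 and 1.41 (SD 0.60). That median, with an error of 0.14 from the median absolute deviation, lay under the bound of 0.25 written beforehand against this explanation. It was left open because the list had left out Pdk4 (2.17) and Fgf21, fasting response genes that rose here, a reason found after the value was seen. The operation and food intake cannot be told apart here, because no measure of feeding was given.

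The real split of the 4 arrays gave 916 changed probe sets and the highest of the other splits gave 0. The real split was the 1 split of 3 with as many, and 3 splits are too few for a share under 0.05. Each other split also put a sham and a hepatectomy array into the same group, so an effect of the operation widened the spread within groups. The 0 therefore does not show what arises without an effect.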
